A study of Mus musculus with 6 samples.

How the data were processed

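Polyadenylated RNA of isolated mouse hepatocytes was sequenced in 6 samples, 3 senescent and 3 healthy, grouped by the titles in the labels. Per the labels' protocols, the cells were freed by a collagenase perfusion, filtered and purified on a density gradient, and libraries were made from 500 ng of total RNA with a strand-specific kit and 10 cycles of PCR. Nothing says whether each sample is a separate animal, so p-values measure the spread between these samples. The labels give the AhCre transgene and the conditional Mdm2 allele for the senescent mice and absence of the transgene for the controls, whose Mdm2 genotype is not given in the sources used here. Presence of Cre and deletion of Mdm2 therefore cannot be separated.

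The values are read counts per gene in a single table that the authors deposited, whole numbers with no normalisation. Per the submitters' processing notes the tools were FastQC, MultiQC 1.3, cutadapt 1.16, STAR 2.7.1a, featureCounts and DESeq2 1.34.0, with the mouse build GRCm38. The annotation release, the strand setting and any filters are not given in the sources used here, so overlapping and antisense genes, and genes with near-identical copies, are uncertain. Of the table's 6 columns, 5 bear the exact code of a sample. The remaining column was taken as healthy replicate 2, whose code in the labels differs from it in a single letter. Results without that library were 2095 genes higher and 2096 lower. The table has 0 rows that name no gene. Symbols were found for 31976 IDs (99.7%), and where 2 IDs shared a symbol it stayed with the more abundant. Coordinates and exonic lengths come from GENCODE release M21 on GRCm38, which is not necessarily the authors' release.

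Total counts were 31896760, 32210591 and 29992707 in senescent replicates 1, 2 and 3 and 33267299, 28799392 and 31125316 in healthy replicates 1, 2 and 3. A count of 0 in a library allows up to 3 counts, or 0.084 to 0.117 CPM. Albumin took 5.51% to 5.96% of counts in senescent and 7.26% to 8.87% in healthy libraries, and the 10 most abundant genes 16.6% to 16.8% and 19.2% to 21.1%. TMM factors were 1.07 to 1.15 and 0.893 to 0.909. No library looked like a second copy of another: chi-square statistics of their counts exceeded their degrees of freedom many times over in every pair.

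Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, two-sided, after filterByExpr (minimum count 10, minimum total 15) and TMM scaling, with no covariate. P-values were adjusted by Benjamini-Hochberg over 12949 genes and called under 0.05. The SE of a log2 fold change is its size over the square root of F. Rank tests were not used, since 3 against 3 samples cannot go below p = 0.1 in an exact permutation test. In all, 42 gene lists had been fixed before the data were examined, and 41 with at least 3 tested members were tested by camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists. Camera asks whether a list moves more than other genes. It called 20 lists, and 1, the p53 targets, with the correlation estimated from the data. Fry, which called 28 lists, tests whether a list's genes move on balance one way and does not compare them with other genes. The lists overlap in places.

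Genes named in the text were chosen by a rule set before the data were examined: Mdm2, Trp53 and Cdkn1a; the 10 largest rises and 10 largest falls among called genes of at least 10 CPM whose groups do not overlap and whose symbols are not predicted or pseudogene names; the 4 largest rises and falls in mean CPM; and from each list the 2 risen and the 2 fallen members with the smallest p, or the 2 most abundant where none passed. Alternatives planned in advance were DESeq2 1.42.0, limma-voom, size factors of the DESeq2 type, total library size, no filter, a filter at a mean of 1 CPM, removal of the 50 most abundant or of mitochondrial genes, an adjusted p under 0.01, the replicate number as a block, each library left out, camera with an estimated correlation and fry. Removal of a trend on exonic length or on GC content was added after the data had been seen.

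The tests were tried on simulated counts for 12822 tested genes, with 200 genes changed, as many up as down. Counts were drawn from the means of both groups together, the library sizes and dispersions taken from their trend on abundance. In the simulated senescent against healthy comparison, 76.0% of 100 genes changed 2-fold and 98.0% of 99 genes changed 4-fold were called in the right direction, with 7 false calls among 12623 unchanged genes. Such few and balanced changes do not test the scaling, or the false calls, of the real comparison, where 41.1% of genes were called.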

Results

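RNA was sequenced from hepatocytes, the metabolic cells of the liver, isolated by collagenase perfusion from mice of 10 to 12 weeks of age. In 3 samples, called senescent, the mice carried the AhCre transgene and a conditional Mdm2 allele on both chromosomes. Their 3 controls, called healthy, lacked the transgene. AhCre is a Cre recombinase whose promoter answers to ligands of the aryl hydrocarbon receptor, and all 6 samples came from mice given such a ligand, β-naphthoflavone, at 20 mg/kg for 48 h. Mdm2 encodes the ubiquitin ligase that keeps the transcription factor p53 low. Total counts per library were 29992707 to 32210591 in the senescent and 28799392 to 33267299 in the healthy libraries. Of the genes listed, 13670 had 0 counts in every library and 12949 had enough counts to be tested. Values are CPM, counts over the scaled library size, as mean ± SD over n = 3 libraries per group, and log2 fold changes are senescent minus healthy, ± SE.

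The targeted gene was read first. Mdm2 (ENSMUSG00000020184; GRCm38 chromosome 10, 117688875 to 117710758) had 465, 463 and 501 CPM in senescent replicates 1, 2 and 3, against 19.03, 22.7 and 22.0 CPM in the healthy ones. Its log2 fold change was 4.49 ± 0.14 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.3e-07). The count spans the whole gene and the deleted part is not given in the sources used here, so it does not check the deletion. Mdm2 is itself a textbook target of p53. Cdkn1a (ENSMUSG00000023067; chromosome 17, 29090976 to 29100727), which encodes the cell cycle inhibitor p21, went from 35.6 ± 17.0 to 717 ± 60.0 CPM, a rise of 20.2-fold (edgeR adjusted p = 4.4e-05). Trp53 (ENSMUSG00000059552; chromosome 11, 69580359 to 69591873), the gene of p53, had 15.1 ± 0.826 CPM in healthy and 18.0 ± 2.27 CPM in senescent cells (edgeR adjusted p = 0.15). With total library size in place of TMM scaling its log2 fold change was 0.56 and passed (edgeR adjusted p = 0.011).

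The comparison asks which transcripts differ between senescent and healthy hepatocytes. In edgeR's test 2644 genes rose and 2680 fell among the 12949, or 41.1% of them, and 1352 of the risen and 899 of the fallen genes changed at least 2-fold. At least 8-fold changes were found for 278 risen and 50 fallen genes. The 2 groups' values did not overlap for 6988 genes (54.0%), where chance gives 10%. The first principal component held 78.7% of the variance and separated the groups. Scaling decides the balance of the calls: with total library size, 4861 genes rose and 1285 fell, so that 79.1% of the calls were rises against 49.7% with TMM. That scaling put the median log2 fold change of all genes at 0.33, against 0.01 with TMM, and changes below are relative to TMM. Without senescent replicate 3, 1489 genes fell.

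The largest rises among genes of at least 10 CPM were nearly from nothing. Prrg4 had 0 counts in all healthy libraries and 27.2 ± 3.81 CPM in senescent ones. That is 756-fold higher against a floor of 3 counts over the group, and at least 614-fold by the 95% counting interval used for the genes below. St14, which encodes the membrane protease matriptase, went from 3 counts in the healthy libraries together to 23019 in the senescent ones, a ratio of 6132 (2098 to 29735), with the 95% counting interval in brackets. The ratio was 5498 (986 to 217191) for the mitochondrial creatine kinase gene Ckmt1, 5499 (987 to 217222) for Inka2 and 2258 (772 to 10949) for Cpt1c, a carnitine palmitoyltransferase gene known from neurons. It was 1879 (337 to 74238) for Cercam, 1460.0 (499 to 7082) for Psrc1, 1469.6 (407 to 12139) for the adenylate kinase gene Ak1 and 567 (194 to 2753) for Pqlc3. Sec14l5 rose from 0.0697 ± 0.0564 to 34.5 ± 6.14 CPM. The fitted changes of these 10 genes passed edgeR's test with adjusted p of at most 1.2e-05. Such intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules.

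Among the largest falls, Hamp2, a paralog of the hepcidin gene, went from 666 ± 84.7 to 10.3 ± 4.15 CPM. Hao2, a peroxisomal hydroxyacid oxidase gene, went from 20.99 ± 7.59 to 0.306 ± 0.235 CPM, and G0s2, which encodes an inhibitor of adipose triglyceride lipase, from 60.4 ± 20.8 to 1.71 ± 1.158 CPM. Csad, whose enzyme acts in taurine synthesis, went from 249.9 ± 94.4 to 11.7 ± 1.57 CPM, Depp1 from 73.5 ± 12.2 to 6.22 ± 0.863 CPM, Upp2 from 223 ± 78.6 to 20.4 ± 4.44 CPM and Acot3 from 55.3 ± 40.3 to 2.57 ± 1.69 CPM. The hydroxysteroid sulfotransferase genes Sult2a1, Sult2a3 and Sult2a5 had log2 fold changes of -4.15 ± 0.63, -6.20 ± 0.81 and -3.92 ± 0.48, but their near-identical copies can share reads and the split between them is uncertain. These 10 falls had edgeR adjusted p of at most 0.0014. The 4 largest rises in mean CPM were those of the tubulin gene Tubb4b, from 135 ± 11.8 to 2612 ± 181 CPM, the carboxylesterase gene Ces2e, from 149 ± 24.1 to 2080.4 ± 159 CPM, Serpina3n, from 643 ± 264 to 2879 ± 877 CPM, and the P450 gene Cyp3a11, from 1867 ± 431 to 3498 ± 677 CPM. Tubb4b has a processed copy and Ces2e and Cyp3a11 have close paralogs. The 4 largest falls included Alb, the gene of serum albumin, from 90316 ± 9846 to 51519.9 ± 3860.4 CPM (edgeR adjusted p = 0.02). Trf (transferrin) went from 26345 ± 3645 to 14055 ± 1119 CPM, Apoe from 22113 ± 2675 to 13011 ± 1209.6 CPM and Serpina1c, one of several alpha-1-antitrypsin paralogs, from 10995 ± 748 to 5753 ± 477 CPM. The call of Alb was lost when any single senescent replicate was left out (edgeR adjusted p 0.060 to 0.084 in those fits) and with a trend on gene length removed (log2 fold change -0.63, adjusted p = 0.059), and that of Apoe without senescent replicate 2 (0.068) or 3 (0.058) and with total library size (0.057).

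**Figure D1:**
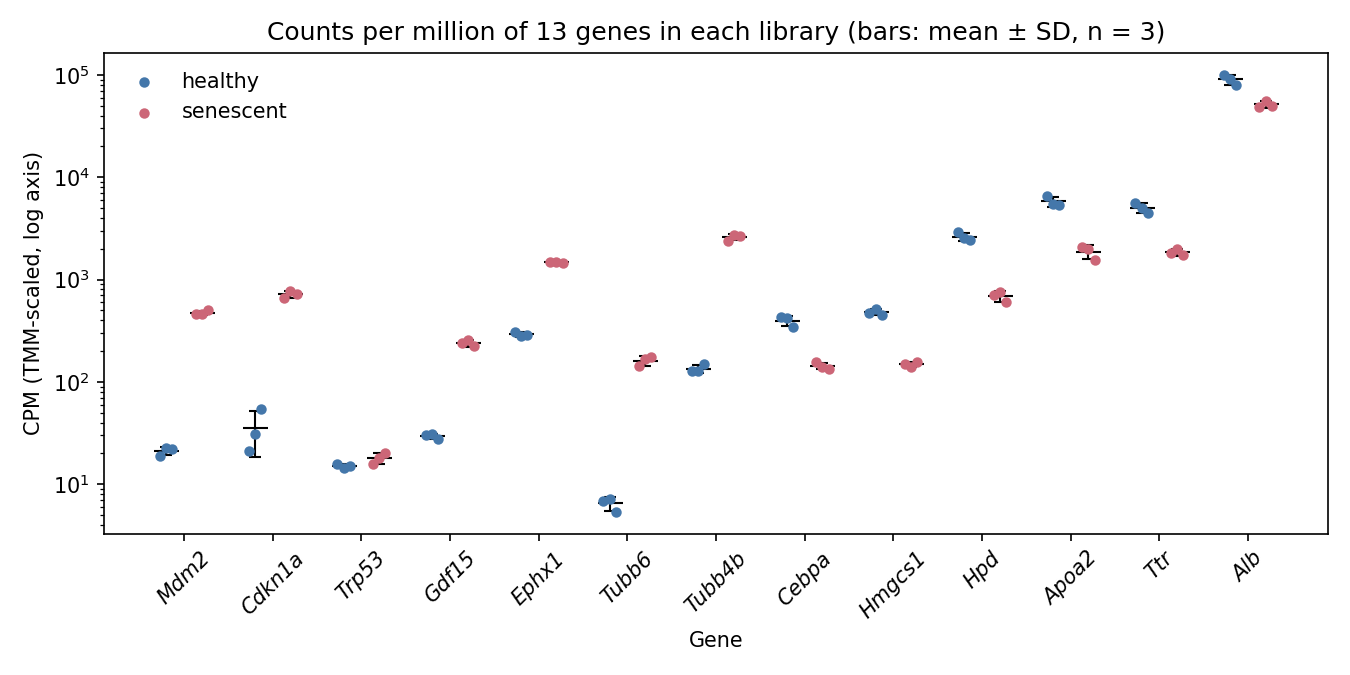
CPM (log axis) of 13 genes in each of the 3 healthy and 3 senescent libraries, with bars for mean ± SD. Mdm2 and Cdkn1a were near 21.2 and 35.6 CPM in healthy and 476 and 717 CPM in senescent libraries, while Alb went from 90316 to 51520 CPM.

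Genes known as p53 targets rose together. Of 48 tested members of that list, 41 rose, 1 fell and 6 did not pass (42 and 1 adjusted over the list alone), with a median log2 fold change of 3.17 (camera adjusted p = 7.1e-85, adjusted p = 0.015 with an estimated correlation). This was the only list called with an estimated correlation. Gtse1 went from 0.409 ± 0.0940 to 143 ± 19.7 CPM and Eda2r, a receptor of the tumour necrosis factor family, from 0.392 ± 0.0691 to 99.8 ± 16.1 CPM. The single member that fell was Sesn1, from 11.4 ± 0.543 to 6.61 ± 0.897 CPM. The p53 list includes Cdkn1a, Psrc1 and Ak1. Of 22 macrophage markers 8 rose, with a median of 1.00 (camera adjusted p = 0.012, adjusted p = 0.70 with an estimated correlation, 0.062 with total library size and 0.10 by fry).

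The senescence markers moved in both directions, and the list does not say which direction each member takes in senescence. Camera and fry, as used here, test it in a single direction. Of 19 tested, 8 rose and 2 fell (9 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.09, adjusted p = 0.49 with an estimated correlation). It was called in 3 of 17 other settings: with no filter (camera adjusted p = 0.026), without senescent replicate 2 (0.031, median 0.93 against 0.36) and by fry (adjusted p = 0.0052). Besides Cdkn1a, Bcl2l1, which encodes an inhibitor of apoptosis, rose from 32.2 ± 3.15 to 105 ± 19.2 CPM. Falls were those of Hmgb1, a chromatin protein gene, from 121 ± 5.16 to 84.1 ± 3.38 CPM and of Dpp4 from 119 ± 9.36 to 94.9 ± 5.72 CPM. Those 2 falls were not called with total library size (edgeR adjusted p = 0.11 and 0.91). The call of Dpp4 was also lost with no filter (0.077) and without senescent replicate 1 (0.18), 2 (0.16) or 3 (0.12) or healthy replicate 2 (0.082) or 3 (0.088). Of 37 genes of the senescence-associated secretory phenotype, the factors that senescent cells release, 17 rose and 8 fell (18 and 8 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 0.0027, adjusted p = 0.49 with an estimated correlation). The stress cytokine gene Gdf15 went from 29.5 ± 1.67 to 240.0 ± 18.4 CPM and the growth factor gene Pdgfa from 3.61 ± 0.714 to 32.8 ± 4.58 CPM. Igfbp2 fell from 509 ± 57.4 to 194 ± 29.7 CPM and Angptl4, also a PPAR-alpha target, from 132 ± 47.9 to 18.8 ± 8.36 CPM. The CPM of the whole list summed to 2849.7 ± 193 CPM in healthy and 1893 ± 194 CPM in senescent libraries, so its sum and its median differ in sign. Without healthy replicate 3 its median was 1.23. In the same libraries 8 of 22 macrophage and 11 of 19 stellate cell genes rose, with medians of 1.00 and 1.11 (camera adjusted p = 0.012 and 0.011, adjusted p = 0.70 and 0.60 with an estimated correlation, 0.062 for each with total library size). Spp1, which rose, is in this list and in the cholangiocyte list. Of 22 TGF-beta response genes 6 rose, among them Ccn1 and Pmepa1, and 3 fell, among them Smad6 (6 and 3 adjusted over the list alone; camera adjusted p = 0.33).

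Cell cycle genes rose from low levels. Of 31 G2 and mitosis genes 29 rose, 0 fell and 2 did not pass (29 and 0 adjusted over the list alone), with a median of 2.88 (camera adjusted p = 1.2e-07, adjusted p = 0.58 with an estimated correlation). The mitotic kinase gene Ttk went from 0.0697 ± 0.0564 to 2.22 ± 0.360 CPM and Hmmr from 0.200 ± 0.0896 to 2.80 ± 0.936 CPM. Summed over all members in the table, the list held 16.5 ± 5.55 CPM in healthy and 81.3 ± 31.3 CPM in senescent libraries, below Cdkn1a alone. Of 31 DNA replication and S phase genes 14 rose and 3 fell (17 and 3 adjusted over the list alone), with a median of 0.88 (camera adjusted p = 0.0089, adjusted p = 0.67 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit gene, went from 4.77 ± 1.78 to 39.1 ± 7.78 CPM and the replicative helicase gene Mcm7 from 13.3 ± 2.52 to 30.9 ± 3.19 CPM. Tk1, a gene of nucleotide supply, fell from 28.0 ± 11.9 to 10.3 ± 1.59 CPM. Macrophage markers, described further on, moved the same way as these lists, with 284 ± 105 CPM in healthy and 526 ± 155 CPM in senescent libraries. Among 26 DNA damage and repair genes 8 rose, Gadd45a and Atr with the smallest p, and 2 fell, among them Parp1 (10 and 2 adjusted over the list alone; camera adjusted p = 0.19). Fry called this list (adjusted p = 0.020). With total library size 16 of these genes rose and 0 fell, with a median of 0.63 against 0.32, and the fall of Parp1 was not called (edgeR adjusted p = 0.051).

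Lipid and sterol genes fell. Of 36 fatty acid oxidation and PPAR-alpha target genes 29 fell and 0 rose, with a median of -0.90 (camera adjusted p = 3.7e-09, adjusted p = 0.49 with an estimated correlation). The acyl-CoA synthetase gene Acsl1 went from 853 ± 87.9 to 284 ± 35.9 CPM and Hadh from 295 ± 31.1 to 108 ± 14.7 CPM. Of 23 fatty acid and triglyceride synthesis genes 19 fell and 0 rose, with a median of -1.14 (camera adjusted p = 3.7e-09, adjusted p = 0.49 with an estimated correlation). Pklr, the liver pyruvate kinase gene, went from 362 ± 41.3 to 58.2 ± 18.0 CPM and the elongase gene Elovl5 from 558 ± 56.2 to 182 ± 20.3 CPM. Of 26 cholesterol synthesis genes 22 fell and 0 rose, with a median of -1.08 (camera adjusted p = 5.3e-11, adjusted p = 0.49 with an estimated correlation). Hmgcs1 went from 481 ± 33.3 to 149 ± 8.45 CPM and Mvd from 38.3 ± 7.23 to 8.73 ± 0.0360 CPM, both in the mevalonate pathway. The falls adjusted over the list alone were 29, 20 and 23. Beside these and the falling lists below, the summed CPM of other-cell markers was 1.86-fold higher for macrophages and 2.22-fold higher for stellate cells, sums that were not tested. For the members of these other-cell lists camera gave adjusted p = 0.012 and 0.011 (adjusted p = 0.70 and 0.60 with an estimated correlation, 0.062 for each with total library size). With total library size the medians of the lipid and sterol lists were -0.59, -0.83 and -0.77.

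The amino acid, gluconeogenesis and bile acid lists were called lower by camera, and the glycolysis list was not called. Of 40 urea cycle and amino acid catabolism genes 23 fell and 3 rose (23 and 3 adjusted over the list alone), with a median of -0.73 (camera adjusted p = 2.3e-06, adjusted p = 0.55 with an estimated correlation). The urea cycle gene Otc went from 412 ± 60.9 to 105 ± 12.2 CPM and the tyrosine catabolism gene Hpd from 2627 ± 256 to 686 ± 80.0 CPM, whereas Ftcd rose from 387 ± 88.6 to 873 ± 58.6 CPM and Gpt from 374 ± 123 to 729 ± 36.4 CPM. Of 16 gluconeogenesis and glycogen genes 10 fell and 0 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.49 with an estimated correlation). G6pc, the catalytic subunit gene of glucose-6-phosphatase, went from 454 ± 44.0 to 90.6 ± 26.8 CPM and the glycogen synthase gene Gys2 from 94.5 ± 5.65 to 52.6 ± 7.36 CPM. Of 27 bile acid genes 14 fell and 4 rose (14 and 4 adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.49 with an estimated correlation). Slc27a5, whose enzyme activates bile acids with coenzyme A, went from 1441 ± 41.7 to 480.4 ± 36.9 CPM and the bile acid uptake carrier gene Slc10a1 from 611 ± 47.4 to 211 ± 40.4 CPM. The canalicular phospholipid transporter gene Abcb4 rose from 256 ± 30.3 to 703 ± 58.1 CPM and the efflux pump gene Abcc4 from 3.25 ± 1.00 to 13.1 ± 2.55 CPM. Scaled to total library size, 17 urea cycle and amino acid catabolism genes fell and 4 rose, with a median of -0.42. On that scale 6 gluconeogenesis genes fell and 3 rose, and 9 bile acid genes fell and 7 rose. Of 19 glycolysis genes 4 rose, Ldhb and Slc2a1 with the smallest p, and 5 fell, Aldoc and Eno1 with the smallest p (5 and 6 adjusted over the list alone; camera adjusted p = 0.85). Their median was -0.03, their mean 0.24, and their median 0.28 with total library size.

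Secreted plasma proteins followed Alb. Of 40 genes 23 fell and 2 rose (24 and 2 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 1.6e-04, adjusted p = 0.49 with an estimated correlation). Apoa2 went from 5805 ± 657 to 1878 ± 279.8 CPM and the transthyretin gene Ttr from 5036 ± 612 to 1856 ± 138 CPM. The complement gene C6 rose from 5.90 ± 2.55 to 20.4 ± 7.13 CPM and the clotting factor gene F12 from 597 ± 75.8 to 934 ± 35.6 CPM. Summed over the list, plasma protein transcripts took 267851 ± 16498 CPM in healthy and 168761 ± 10807 CPM in senescent libraries. With total library size 15 of these genes fell and 5 rose, with a median of -0.33. Of 26 periportal genes, those most active near the portal vein, 14 fell and 2 rose (14 and 2 adjusted over the list alone; camera adjusted p = 1.6e-04, adjusted p = 0.55 with an estimated correlation); this list shares members with other lists. Sds went from 307 ± 58.2 to 47.4 ± 16.5 CPM and Hsd17b6 from 249.7 ± 17.8 to 62.1 ± 9.64 CPM, while Ftcd rose. Without healthy replicate 1 the periportal median was -0.47. Of 26 pericentral genes 7 fell, Cyp2c37 and Rgn with the smallest p, and 2 rose, Slc1a4 and Slc13a3 (6 and 2 adjusted over the list alone; camera adjusted p = 0.47). The pericentral median of -0.29 turned to 0.02 with total library size and ran from -0.43 to -0.058 with single libraries left out, and whether the zones differ was not tested. Among 21 hepatocyte transcription factor genes 6 fell and 2 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.13). Cebpa went from 398 ± 44.5 to 144 ± 11.04 CPM and the nuclear receptor gene Nr1i3 from 210.2 ± 35.8 to 61.7 ± 11.4 CPM, whereas Esrra rose from 23.9 ± 10.5 to 70.5 ± 2.08 CPM and Foxa3 from 39.3 ± 14.0 to 64.0 ± 3.67 CPM. The call of Foxa3 was lost without senescent replicate 1 (edgeR adjusted p = 0.062), 2 (0.084) or 3 (0.082) or healthy replicate 1 (0.093) or 2 (0.092). The list's median of -0.26 turned to 0.05 with total library size and was -0.093 without senescent replicate 3 and -0.17 without healthy replicate 2, and fry called the list (adjusted p = 0.039).

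Genes of drug metabolism and redox defence split. Of 44 cytochrome P450 and xenobiotic genes 20 fell and 10 rose (21 and 11 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.029, adjusted p = 0.49 with an estimated correlation). The carboxylesterase gene Ces3b went from 481 ± 23.2 to 125 ± 10.8 CPM and the sulfotransferase gene Sult1a1 from 411 ± 108 to 122 ± 15.9 CPM. Gstp1 rose from 346 ± 103 to 1610.3 ± 166 CPM and Cyp2d9 from 46.2 ± 16.9 to 162 ± 39.4 CPM, both in families with close copies. The call of this list was lost with the replicate number as a block (camera adjusted p = 0.060) and with a trend on gene length removed (median -0.23, 0.13). With total library size the median was -0.01, with 12 risen and 14 fallen. Of 24 NRF2 targets, genes of the response to electrophiles, 13 rose and 3 fell (14 and 3 adjusted over the list alone), with a median of 0.79 (camera adjusted p = 0.0071, adjusted p = 0.49 with an estimated correlation). The epoxide hydrolase gene Ephx1, also in the p53 list, went from 291 ± 15.4 to 1470.5 ± 26.7 CPM and the sulfiredoxin gene Srxn1 from 36.6 ± 5.48 to 229 ± 69.8 CPM. Of macrophage genes 8 of 22 rose, with a median of 1.00 (camera adjusted p = 0.012, adjusted p = 0.70 with an estimated correlation, 0.062 with total library size and 0.10 by fry), and of stellate cell genes 11 of 19, with a median of 1.11 (camera adjusted p = 0.011, adjusted p = 0.60 with an estimated correlation, 0.062 with total library size). Me1, which also serves lipid synthesis, fell from 336 ± 36.3 to 177 ± 9.58 CPM and the catalase gene Cat from 2428 ± 134 to 1603 ± 81.7 CPM, a call lost with total library size (edgeR adjusted p = 0.097) and without senescent replicate 1 (0.051). The ligand given to all mice acts on the aryl hydrocarbon receptor, and of 9 of its targets 4 rose, Nqo1 and Ugdh with the smallest p, and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.89). Their median was -0.35 and mean -0.09, while the test's direction was up.

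Genes of the energy and protein synthesis machinery fell by small amounts with TMM scaling. Of 34 nuclear oxidative phosphorylation genes 27 fell and 0 rose (30 and 0 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 1.3e-05, adjusted p = 0.66 with an estimated correlation). Sdhc went from 186 ± 17.8 to 107 ± 7.35 CPM and Ndufb5 from 68.3 ± 12.4 to 35.2 ± 2.99 CPM. Of 45 cytosolic ribosomal protein genes 29 fell and 3 rose (33 and 3 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 7.7e-04, adjusted p = 0.70 with an estimated correlation). Rplp1 went from 355 ± 55.0 to 169.9 ± 14.8 CPM and Rps2 from 735 ± 88.4 to 386 ± 33.1 CPM, while Rps19 rose from 110.4 ± 16.2 to 187 ± 8.28 CPM and Rpl9 from 219.6 ± 16.3 to 344 ± 13.7 CPM. These genes have many processed copies that can take their reads. On the scale of total library size 12 oxidative phosphorylation genes fell and 1 rose, with a median of -0.34. Only 4 ribosomal protein genes fell and 3 rose on that scale, with a median of -0.13. The ribosomal protein list took 0.84% to 0.91% of counts in senescent and 0.80% to 1.00% in healthy libraries. With a trend on gene length removed the ribosomal call was lost (camera adjusted p = 0.067). The oxidative phosphorylation median was then -0.38 (57.8% of its size, camera adjusted p = 0.0019). Of 13 mitochondrially encoded genes 1 fell and 0 rose (0 and 0 adjusted over the list alone; camera adjusted p = 0.64).

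Fetal and dedifferentiation genes rose: 12 of 20 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.93 (camera adjusted p = 4.7e-05, adjusted p = 0.49 with an estimated correlation). Medians of other-cell markers were 1.11 for stellate cells and 1.00 for macrophages (camera adjusted p = 0.011 and 0.012, adjusted p = 0.60 and 0.70 with an estimated correlation, 0.062 for each with total library size). They were 1.00 for cholangiocytes (0.71 to 1.66 with single libraries left out) and 0.12 for endothelium, lists that were not called (camera adjusted p = 0.27 and 0.64). The tubulin gene Tubb6 went from 6.49 ± 0.988 to 161 ± 17.7 CPM and Tnfrsf12a, the receptor of the cytokine TWEAK, from 5.04 ± 0.862 to 61.4 ± 22.0 CPM. Of 21 YAP target genes 7 rose, Ccn1 and Crim1 with the smallest p, and 3 fell, Amotl2 with the smallest p (7 and 3 adjusted over the list alone; camera adjusted p = 0.22). Among 26 immediate early and dissociation stress genes 8 rose, such as Klf6 and Egr1, and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.13); the list was called without healthy replicate 3 (median 0.64, camera adjusted p = 0.031) and by fry (0.022). Fry also called the YAP targets (adjusted p = 0.028).

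**Figure D2:**
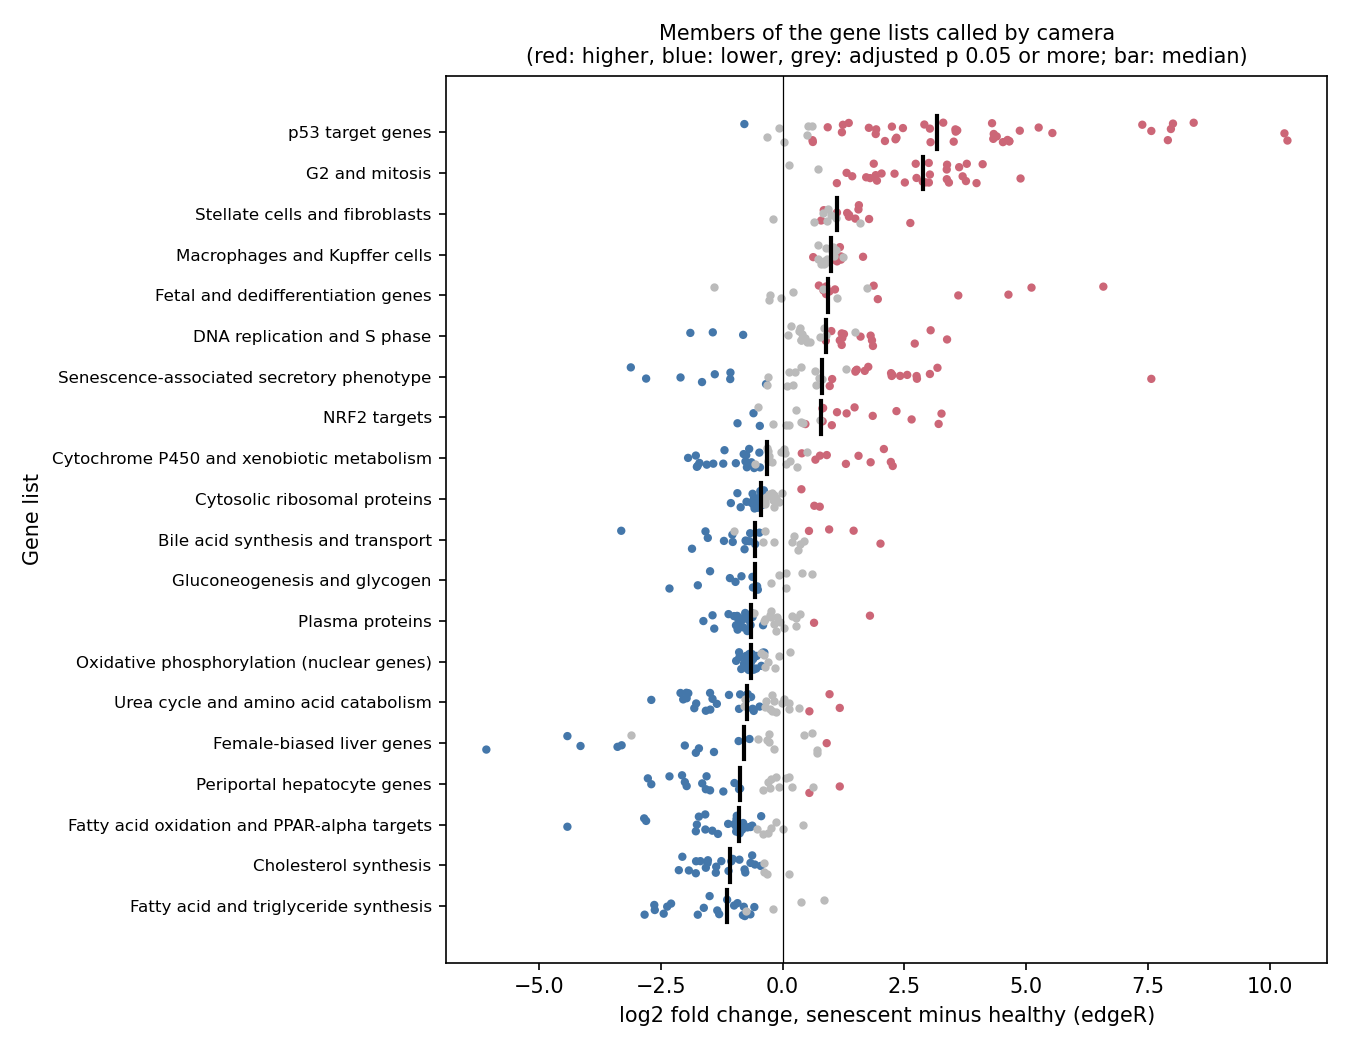
Log2 fold change of each tested member (points) of the 20 lists called by camera, with the median as a black bar; red and blue points passed edgeR's test upwards and downwards and grey points did not. Medians ran from -1.14 for fatty acid and triglyceride synthesis to 3.17 for p53 targets; only the p53 call held with an estimated correlation (adjusted p = 0.015), and with total library size all 20 medians keep their sign, the cytochrome P450 median being -0.01.

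Inflammatory lists were not called with all libraries. Of 32 acute phase genes 4 rose and 6 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.52): Cd14 and the oncostatin M receptor gene Osmr rose, while the hepcidin gene Hamp went from 1624 ± 6.34 to 446 ± 134 CPM and Crp from 479 ± 125 to 191 ± 43.4 CPM. Without healthy replicate 1 this list was called lower (median -0.63, camera adjusted p = 0.026). Of 29 type I interferon genes 3 rose and 7 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.64). Cmpk2 rose from 5.21 ± 1.31 to 73.5 ± 9.74 CPM and Ifih1 from 31.4 ± 3.71 to 57.2 ± 1.37 CPM, while Stat2 and Rtp4 fell, calls lost for Stat2 with total library size (edgeR adjusted p = 0.22) and for Rtp4 without senescent replicate 3 (0.053). Of 23 MHC and interferon-gamma genes 2 rose, the peptide transporter gene Tap1 from 27.1 ± 6.38 to 96.2 ± 1.81 CPM and the MHC class I activator gene Nlrc5 from 17.9 ± 4.10 to 68.5 ± 9.60 CPM, and 6 fell, Cxcl9 and Psmb10 with the smallest p (2 and 6 adjusted over the list alone; camera adjusted p = 0.69). The median of the MHC list was 0.07 while its mean was -0.04 and the test's direction down, and the interferon median of -0.20 turned to 0.11 with total library size. Of 25 endoplasmic reticulum and integrated stress genes 1 rose, Atf3, and 6 fell, Atf5 and Shmt2 with the smallest p (1 and 6 adjusted over the list alone; camera adjusted p = 0.22), with a median of -0.13 that turned to 0.18 with total library size. Without healthy replicate 1 this list too was called lower (median -0.37, camera adjusted p = 0.047).

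Markers of other liver cells were measured in the same libraries. Of 22 macrophage and Kupffer cell genes 8 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 1.00 (camera adjusted p = 0.012, adjusted p = 0.70 with an estimated correlation). Cd163 went from 3.20 ± 1.31 to 10.0 ± 4.12 CPM and Mpeg1 from 46.4 ± 2.05 to 71.6 ± 11.9 CPM. Scaled to total library size, 20 of them rose, but the call of the list was lost (camera adjusted p = 0.062). The macrophage sums of senescent replicate 2 and healthy replicate 2 were close, at 372 and 366 CPM. Of 19 stellate cell and fibroblast genes 11 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.60 with an estimated correlation), from a sum of 23.0 ± 4.99 CPM in healthy and 50.9 ± 10.2 CPM in senescent libraries, with Reln from 2.10 ± 0.231 to 5.39 ± 0.186 CPM and Pdgfra from 0.133 ± 0.0619 to 0.832 ± 0.104 CPM. This call too was lost with total library size (camera adjusted p = 0.062), and with a filter at a mean of 1 CPM (0.053). Of 5 neutrophil genes 4 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.062). S100a9 went from 0.207 ± 0.166 to 1.17 ± 0.107 CPM and Ltf from 0 to 49 counts, 13.1-fold higher against a floor of 3 counts over the group. The neutrophil list was called without senescent replicate 2 (camera adjusted p = 0.032), healthy replicate 1 (0.031) or healthy replicate 2 (0.049), with the length trend removed (0.044) and by fry (0.0061). The monocyte and dendritic cell list had 2 of 7 risen (1 adjusted over the list alone; camera adjusted p = 0.15), Chil3 among them, going from 3 to 43 counts (ratio 11.5 (3.67 to 57.7)). It was called without senescent replicate 2 (camera adjusted p = 0.047) and, close to the threshold, by fry (0.0499). Sinusoidal and vascular endothelium had 3 of 24 risen, Cdh5 with the smallest p, and 1 fallen (0 and 0 adjusted over the list alone; camera adjusted p = 0.64). Cholangiocyte genes had 4 of 10 risen, Spp1 and Krt19 with the smallest p, and 1 fallen (4 and 1 adjusted over the list alone; camera adjusted p = 0.27); it was called with no filter (0.049) and by fry (0.022). Erythroid genes had 0 of 7 risen and 1 fallen, Klf1 (0 and 1 adjusted over the list alone; camera adjusted p = 0.96), with a median of 0.97 and a test direction of down. Only 2 lymphocyte genes could be tested, too few for the list test: Ighm had 6.22 ± 4.93 CPM in healthy and 2.49 ± 1.47 CPM in senescent cells and Igkc 0.655 ± 0.338 CPM in healthy and 1.72 ± 0.841 CPM in senescent cells, and neither passed in edgeR (adjusted p = 0.12 and 0.057). Ighm passed without healthy replicate 3 (0.035) and Igkc without senescent replicate 2 (0.031) or healthy replicate 1 (0.048), with total library size (0.024), DESeq2 (0.027), no filter (0.042), the length trend removed (0.014) and the replicate block (0.049).

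**Figure D3:**
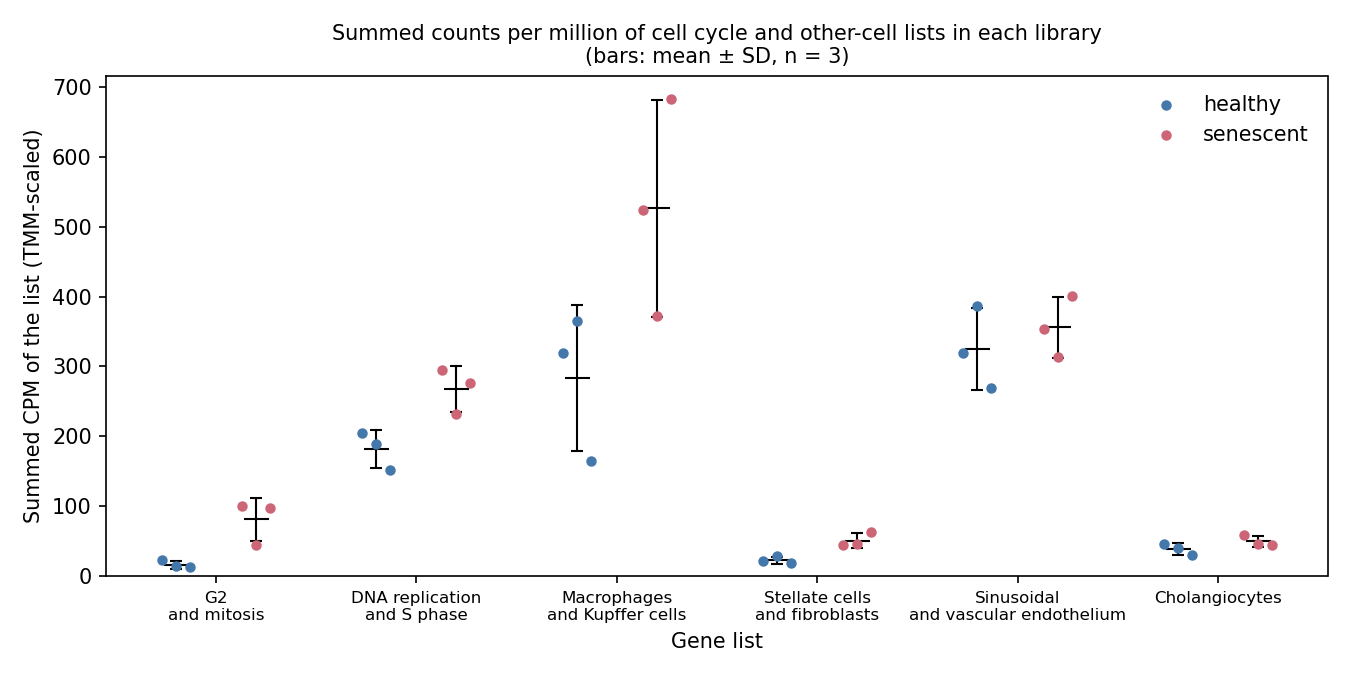
Summed CPM of 2 cell cycle lists and 4 lists of other cell types in each library, healthy and senescent, with bars for mean ± SD (n = 3). The G2 and mitosis sum was 45.1 to 101 CPM in senescent and 12.8 to 22.9 CPM in healthy libraries, and the macrophage sum 372 to 682 against 165 to 366 CPM.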

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

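Across the settings tried, no gene called both there and with the main settings changed sign. Of 159 named genes, 134 stayed on their side of the threshold under every alternative they could be tested in other than the stricter threshold (152 genes could be tested with the 50 most abundant genes left out, 158 with mitochondrial genes left out), 22 lost a call in at least 1, 3 gained one and 0 changed sign. With total library size 4861 genes rose and 1285 fell, and at an adjusted p under 0.01 the counts were 1570 and 1498, the latter by the stricter threshold itself. DESeq2 gave 2793 and 2811, limma-voom 2648 and 2644. Leaving out single libraries gave 1836 to 2691 rises, 1489 to 2789 falls and 1763 to 2399 genes changed at least 2-fold, with the lowest of each without senescent replicate 3. Of the 20 called lists, 19 lost their call with an estimated correlation and 4 in another setting: cytochrome P450 (adjusted p = 0.13 with the length trend removed, range over alternatives 0.0062 to 0.49), ribosomal proteins (0.067 with the length trend removed, range 1.5e-05 to 0.70), macrophages (0.062 with total library size and 0.10 by fry, range 2.5e-04 to 0.70) and stellate cells (0.062 and 0.053 above, range 0.0027 to 0.60). Among lists not called, 11 gained a call in some setting, and 7 of all lists had a median on the other side of 0 with total library size.

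Test directions turned only in lists that were not called. The medians there were -0.062 for aryl hydrocarbon receptor targets with total library size, -0.029 for glycolysis and 0.97 for erythroid genes by fry, 1.03 for erythroid genes with no filter, and, with the length trend removed, 0.31 for mitochondrially encoded and 1.48 for erythroid genes. Over single libraries left out, medians were -0.63 to -0.18 for acute phase, -0.37 to 0.0037 for type I interferon, -0.26 to 0.17 for MHC, -0.72 to 0.28 for aryl hydrocarbon receptor, -0.080 to 0.12 for glycolysis, 0.020 to 0.26 for endothelial and 0.12 to 1.75 for erythroid genes. The cause was not tested, in these or in the counts, except where fewer samples or genes enter by construction.

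With the replicate number as a block, 2576 genes rose, 2625 fell and 2162 changed at least 2-fold. Same-numbered samples did not deviate together (correlations of 0.23, -0.17 and -0.04 across genes), so the numbers are not taken to pair them, and not every sample correlated best with its own number. The cytochrome P450 list (adjusted p = 0.060) and Alb, Stab1 and Ehd3 were not called there, Igkc was, and the erythroid median was 0.94. Genes such as Tiparp, Uroc1, Hsph1, mt-Nd6, Per2, Ccr2, Ltbp2 and Birc3 lost their call in some setting.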

Other observations

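Tests chosen only after the result was seen were those of the Y-linked genes and of the hepatocyte share for the sex-biased lists, the separate tests of the length trend for the ribosomal and the oxidative phosphorylation lists, and both trend removals. The prediction for the length trend had been written for both lists jointly and was split by list after its result was seen.

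Liver genes that differ between the sexes shifted. Of 22 tested female-biased genes 11 fell and 1 rose (11 and 2 adjusted over the list alone), with a median log2 fold change of -0.79 (camera adjusted p = 0.0041, adjusted p = 0.49 with an estimated correlation). Hao2 is among them, and the flavin monooxygenase gene Fmo2 went from 22.1 ± 4.70 to 5.48 ± 0.819 CPM. The member that rose was Xist, the RNA of the inactive X chromosome, from 211 ± 70.3 to 394 ± 53.8 CPM, a call lost without senescent replicate 3 (edgeR adjusted p = 0.063). With total library size 9 female-biased genes fell and 3 rose, with a median of -0.49. Of 15 tested male-biased genes 6 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.12). The male-biased list was called in 5 of 17 other settings: with no filter (camera adjusted p = 0.041), without senescent replicate 1 (0.045), without healthy replicate 2 (0.012, median 2.04 against 0.44), with the length trend removed (0.038) and by fry (0.0061). The urinary protein gene Mup20 went from 39.6 ± 6.11 to 431 ± 164 CPM and Gstp2 from 123 ± 32.0 to 566 ± 53.7 CPM, both with close paralogs, while Selenbp2 and Nudt7 fell. Among 19 circadian clock genes 3 rose, Tef with the smallest p, and 3 fell, Hlf and Cry2 with the smallest p (2 and 3 adjusted over the list alone; camera adjusted p = 0.71), and their median of -0.03 was 0.27 with total library size.

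For the count of called genes, 1 of the 10 splits of the 6 samples into 3 and 3, the real split, gave as many as 5324. The highest of the other 9 gave 0 in edgeR, with 35 to 906 genes at an unadjusted p under 0.05 against 6488 in the real split. With 10 splits no share under 0.05 can be reached. Each of the other splits also mixes senescent and healthy samples, so the difference between the groups adds to the spread within them. Their 0 calls therefore do not measure how many calls chance would give.

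The rise of G2 and mitosis genes in cells described as senescent was weighed first. A difference in scaling is argued against, since the lowest median of the list under 5 scalings was 2.87, above the shift of the median of all genes. Cycling cells of another type remain open, although the cells were filtered and purified on a density gradient: the macrophage list gained 243 CPM, 3.75 times the 64.7 CPM of the mitosis list, a ratio that depends on how abundant each list is and does not show which cells cycle. The summed CPM rose 1.86-fold for macrophages, 2.22-fold for stellate cells and 4.92-fold for mitosis genes. Senescent replicate 2 and healthy replicate 2 had close macrophage sums (372 and 366 CPM) but mitosis sums of 45.1 and 13.9 CPM. Their stellate cell sums were 45.8 and 28.3 CPM. Among senescent libraries, replicate 2 was the lowest in both the macrophage and the mitosis sum. A single pair of libraries does not decide between the explanations. A response of the hepatocytes to the loss of Mdm2, which the design names, is also open and was not tested.

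For the sex-biased genes, male animals or male tissue are argued against, as the summed CPM of Ddx3y, Eif2s3y, Kdm5d and Uty, the 4 Y-linked genes, was 0 in every senescent library and every library held Xist. A lower share of hepatocyte RNA, which would lower both kinds of gene alike, is argued against as the cause of their difference, though not as a part of the fall of female-biased genes, and by a score that restates the pattern: the mean log2 CPM of male-biased minus that of female-biased genes was -0.64 ± 0.61 in senescent and -3.12 ± 0.54 in healthy libraries, and the lowest senescent library exceeded the highest healthy one by 1.49. A candidate explanation is lower growth hormone to STAT5 signalling, a pathway that acts on these programmes in the liver. Of the 5 genes Igf1, Socs2, Cish, Igfals and Ghr, chosen after the pattern but before their own values were seen, 3 fell in edgeR, also with total library size: Socs2 by 2.45, Igfals by 1.65 and Ghr by 0.72 on the log2 scale, while Cish (0.24) and Igf1 (-0.26, or 0.05 with total library size) did not pass. Among other hepatocyte lists, 23 of 40 plasma protein and 14 of 26 periportal genes fell, against 7 of 26 pericentral genes. That 3 of the 5 fell therefore does not separate lower signalling from a general fall of hepatocyte genes. It also does not account for the rise of male-biased genes such as Mup20. Igf1 and Igfals also sit in the periportal list, which fell, and an effect of p53 on these genes by another route was not tested.

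Ribosomal protein and oxidative phosphorylation genes are short, and short genes as a class were lower: the median log2 fold change was -0.49 for 678 genes with under 1 kb of exons and 0.24 for 2185 genes with over 8 kb. With a length trend removed per library the ribosomal median went from -0.44 to -0.20 and its call was lost (camera adjusted p = 0.067, range over alternatives 1.5e-05 to 0.70), so a length trend may account for much of that fall. For oxidative phosphorylation the median went from -0.65 to -0.38 and the call held (camera adjusted p = 0.0019, range 2.9e-07 to 0.66), which argues against length as its whole cause. GC content is argued against for both, as the lists kept at least 91.6% of their medians. Whether the length trend comes from RNA handling or from the cells stays open, since both lists belong to the short genes that set it.

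Reads or transcription running into neighbours were looked for among 277 genes with coordinates and at least an 8-fold rise. Another risen gene lay within 5 kb for 13% of them, inside the 8.30% to 15.9% of 10000 random draws of tested genes. This argues against an excess of risen neighbours over all places together, and cannot tell for a single place. By place, risen neighbours were 10.7% of those downstream on the same strand (18.6% among all tested genes), 40.7% upstream on the other strand (11 of 27; 16.2%), 28.9% downstream on the other strand (20.4%) and 22.6% upstream on the same strand (18.7%). Whether the excess upstream on the other strand exceeds chance was not tested. Neighbours at that place lie off the start of the gene and are transcribed away from it, so reads running past the end of either do not reach the other. Since the strand setting of the counts is not given, reads running into downstream or overlapping genes on the other strand stay open.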
